A study of Homo sapiens with 14 samples.

How the data were processed

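Chromatin accessibility was measured by ATAC-seq in 14 libraries of the human line SUM149PT: 2 each of the unselected line (Parental) and of the clones E, EM1, EM2, EM3, M1 and M2. The deposited count table holds raw counts per library in 65774 consensus regions, made by the authors, whose labels list bcl2fastq 2.20.0.422, cutadapt 1.9.1, Bowtie2 2.2.6, Picard, MACS2 2.1.1, featureCounts, deepTools and hg38 without the role of each. How the regions were merged is not given in the sources used here. The deposited interval file of these regions has a score column that is 0 throughout. The authors' 7 peak lists hold an irreproducible discovery rate score (lowest value 830), a fold enrichment ratio, and -log10 p and -log10 q values, per the file format, and were used only to check which clone each belongs to. The library of each column was taken from its deposited name and the group from the labels.

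Library totals ranged from 8138944 counts (E replicate 1) to 16786823 counts (EM3 replicate 1). Counts were scaled by TMM and tested by edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3) with a model of 7 group means over all 14 libraries, and p-values were adjusted by the Benjamini-Hochberg method. The filterByExpr filter with a minimum count of 10 removed 3 regions and left 65771. A region was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.208. The prior count for log2 values was 2. For the M clones against the EM clones, the libraries of each clone were summed, which gave 65147 regions and a coefficient of variation of 0.522.

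Regions were assigned to the protein-coding gene with the nearest end, within 50 kb, from a RefSeq gene table of the same build; 66.4% of regions had one and 18.8% lay within 1 kb of a gene end. The table gives no strand, so the start of a gene could not be told from its end, and no genome sequence was used here, so motif analysis was not run. There were 20 gene lists of 406 distinct genes: epithelial identity, desmosomes and hemidesmosomes, basal and p63-linked genes, keratins, luminal identity, mesenchymal effectors, EMT transcription factors, collagens and matrix proteases, TGF-beta, Wnt, Hippo and TEAD, AP-1, RUNX and CBFB, NF-kB and cytokines, interferon and antigen presentation, stem and progenitor genes, HOX genes, endothelial markers, blood cell markers and housekeeping genes. Of these genes 405 were in the table and 359 had a region. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between regions, adjusted over 100 tests, and again with the correlation estimated from the data. Camera and edgeR use the spread pooled over all groups.

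The genes named are those that a fixed rule chose. They are the 5 largest and 5 smallest log2 changes among called regions with non-overlapping library values, above-median signal and a gene end within 10 kb, each gene once. Added to these are up to 4 called regions with the smallest p for each list, and the gene-end regions (within 1 kb) of 19 genes of EMT and epithelial identity. Where a gene had several gene-end regions, the one with the highest mean log2 CPM was taken. ZEB2, RUNX1, TP63, KRT14 and KRT18 had no such region. The groups, comparisons, lists, this rule and the alternatives were chosen before the data were examined, except for leaving out the M2 libraries and E replicate 1 together, the list tests without single E libraries, and the counts of regions separating the EM clones without single libraries.

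A fold against a group without counts was computed with a floor of 3 counts over the group, and a ratio with 1 to 3 counts has an exact binomial 95% interval. The position of a clone was its difference from E divided by the difference of the mean of M1 and M2 from E, as a median over regions. For the shared use of E by 2 comparisons, the covariance of their changes was set beside that of 5 simulated draws without change.

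The alternatives were scaling by library totals, DESeq2 size factors or loess offsets, no filter, the DESeq2 1.42.0 Wald test, a log2 limit of 1, a replicate block, only the 4 libraries compared, removal of the median log2 change in each 10 Mb window (at least 20 regions), and leaving out each library or clone in turn. A setting without a library leaves a group with 1 library, which is assumed to vary like the other groups. Relative to TMM, library totals moved the median log2 change by -0.14 (M2 versus E), -0.15 (M2 versus M1) and -0.11 (M2 versus Parental), and loess offsets moved it by 0.15, 0.14 and 0.18; all other shifts were within 0.1.

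The tests were tested on simulated data. With 2 libraries per group, 67 of 65770 regions were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Of these 1.5%, 9% and 59.1% were recovered, and 10 of 56 calls were false, above the 5% aimed at. In the data 43.8% of regions were called in M1 versus E. The adjustment is less strict when so many regions change, so these figures are not the recovery or error of that comparison. Without any change, 4.92% of p-values were under 0.05 and 0.96% under 0.01, and at most 0 regions were called in 5 draws. For clone sums, 100 of 65135 regions were changed 4-fold and 100 were changed 16-fold. Of these 7% and 45% were recovered, with 3 of 55 calls false. In the data 7.1% of regions were called there, so the same limit holds. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the R package data.table (version 1.17.8).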

Results

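Chromatin accessibility was measured by ATAC-seq, in which a transposase places sequencing adapters into open chromatin, in SUM149PT cells and in 6 clones of that line. SUM149PT is an established line from an inflammatory breast cancer that lacks the oestrogen and progesterone receptors, per the labels. The groups were the unselected line (Parental) and the clones E, EM1, EM2, EM3, M1 and M2, with 2 libraries each and 14 libraries in all. The labels do not spell out the clone letters, and the series title places the study in the epithelial-mesenchymal transition (EMT) and its intermediate state. The libraries held between 8138944 counts (E replicate 1) and 16786823 counts (EM3 replicate 1) in 65774 regions with a median width of 407 bp. Values are counts scaled to library size by TMM (CPM), given as mean ± SD with n = 2 libraries, and positions are in hg38. The labels do not say whether the libraries of a clone came from separate cultures, so the p-values measure only the spread between these libraries. Intervals and floors cover counting error only.

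Clones M1 and M2 stood apart from the other groups. Across regions, which are not independent replicates, the group means of log2 CPM of Parental correlated at 0.96 with EM1, 0.93 with EM3, 0.90 with EM2, 0.87 with E, 0.56 with M1 and 0.26 with M2. M1 and M2 correlated at 0.56 with each other. Replicate libraries correlated at 0.87 in E and between 0.95 and 0.97 in the other groups. E replicate 1 carried M2-like signal. It correlated at 0.54 with each M2 library, and E replicate 2 at 0.35 and 0.36. At 12 regions without a single count in the 10 libraries of Parental, EM1, EM2, EM3 and M1, E replicate 1 had 23.12% of the mean M2 level (95% exact Poisson interval 21.19 to 25.17) and E replicate 2 had 1.94% (1.44 to 2.57). Counts of regions that differed from E are therefore also given without E replicate 1, a setting that had been planned.

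**Figure D1:**
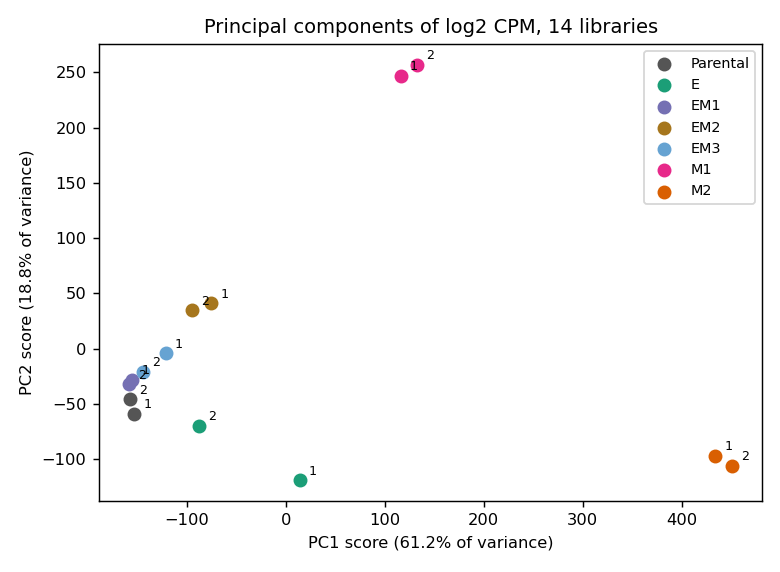
Principal component scores of log2 CPM for 14 libraries, with PC1 (61.2% of the variance) on the x axis and PC2 (18.8%) on the y axis. Points are libraries, colours are groups and digits are replicate numbers; M1 and M2 lie apart, and E replicate 1 lies nearer to M2 than E replicate 2 does.

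**Figure D2:**
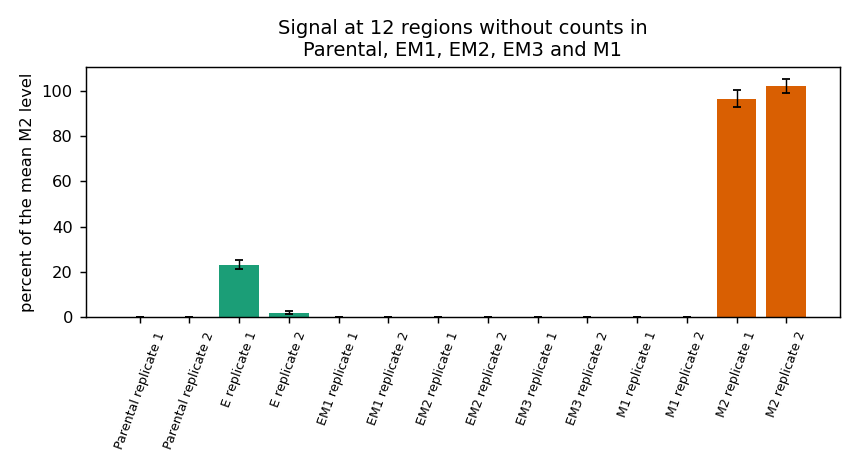
Signal per library, as a percent of the mean M2 level, at the 12 regions without counts in Parental, EM1, EM2, EM3 and M1. Bars start at 0 and whiskers are 95% exact Poisson intervals, with E replicate 1 at 23.12%.

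M1 was compared with E to ask how a clone named M differed in open chromatin from the clone named E. The regions at the ends of genes of epithelial junctions and of their regulators were less accessible in M1. At CDH1, which encodes E-cadherin (chromosome 16, 68738070 to 68738719, inside the gene), accessibility was 35.8 ± 0.15 in E and 2.52 ± 0.20 in M1, a log2 change of -3.83. At GRHL2, a transcription factor of epithelial identity (chromosome 8, 101492217 to 101492855, overlapping an end of the gene), it was 37.2 ± 5.2 in E and 0.822 ± 0.041 in M1. ESRP1, an epithelial splicing factor, fell by 3.26 on the log2 scale, and EPCAM, an epithelial adhesion molecule, fell by 2.37. VIM, the mesenchymal intermediate filament vimentin (chromosome 10, 17228163 to 17228903, overlapping an end), rose from 15.6 ± 8.6 in E to 53.2 ± 0.81 in M1, a log2 change of 1.77. Removing the median change of the surrounding 10 Mb window left VIM at 0.50, no longer past the threshold. Of the other genes fixed in advance, KRT8 (-0.32) and TWIST1 (0.49) did not pass in M1, and FN1 (0.73) passed only in some settings. ZEB1 rose by 0.74, or by 0.30 and not past the threshold with the window median removed. RUNX2 (1.09) and CBFB (0.57) passed, but not with only the 4 libraries compared.

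Among called regions of above-median signal within 10 kb of a gene end and with non-overlapping library values, the 5 largest rises and 5 largest falls in M1 were these. A region inside ESR2, the gene of oestrogen receptor beta (chromosome 14, 64232058 to 64232808), rose from 2.67 ± 0.51 to 59.1 ± 20. The region at an end of GUCY1B1, a subunit of soluble guanylate cyclase (chromosome 4, 155758789 to 155759334), rose from 0.826 ± 0.55 to 25.9 ± 1.2. Regions in or near KANK1, AGXT2 and GALNT6 rose by 4.2, 3.78 and 3.52 on the log2 scale. The same GUCY1B1 and GALNT6 regions also rose in EM3 versus E, by 4.16 and 3.39. A region outside AMOTL2, a regulator of the Hippo pathway (chromosome 3, 134381824 to 134382235), fell from 35.7 ± 6.6 to 0.172 ± 0.057, a log2 change of -7.68. At an end of RBBP8, a DNA repair gene (chromosome 18, 22913746 to 22914214), accessibility fell from 29.8 ± 2.6 to 0.251 ± 0.21, and regions in or near HPGDS, TNNT2 and KCNK5 changed by -6.52, -6.11 and -5.97.

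Gene groups fixed in advance moved in M1 as follows, with regions assigned to the nearest protein-coding gene. Of 133 regions of 28 epithelial identity genes, 8 rose, 79 fell and 46 did not pass the test, and 94 passed when adjusted over the list alone (camera adjusted p = 4e-08 for a shift of the list). Examples are CLDN4, a tight junction protein (-4.94), and SPINT1, an epithelial protease inhibitor (-4.26). Of 99 regions of desmosome and hemidesmosome genes, 5 rose, 54 fell and 40 did not pass (63 adjusted over the list alone, camera adjusted p = 9e-07), with JUP at -5.21 and DSG3 at -5.28. Keratins had 2 regions that rose, 22 that fell and 23 that did not pass (26 adjusted over the list alone, adjusted p = 0.00043), and KRT5 fell by 3.05. Basal and p63-linked genes had 4 that rose, 36 that fell and 41 that did not pass (42 adjusted over the list alone, adjusted p = 0.0015), with a TP63 region (chromosome 3, 189584627 to 189585210, outside the gene) at -3.66. Among 171 regions of mesenchymal effectors, 70 rose, 12 fell and 89 did not pass (83 adjusted over the list alone, adjusted p = 3.5e-06), with a CD44 region at 3.19, PDGFC at 4.53 and THY1 at 4.77, while a region of SPARC fell by 4.94. The same CD44 region also rose in EM1 and EM3, so its rise from E is not particular to M1. With an estimated correlation these 5 lists no longer passed: adjusted p = 0.12 for epithelial identity and desmosomes, adjusted p = 0.39 for keratins, adjusted p = 0.35 for basal genes and adjusted p = 0.092 for mesenchymal effectors. Within 1 kb of gene ends the basal call was lost (adjusted p = 0.061).

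Matrix, cytokine and endothelial lists also shifted upward in M1. Of 117 regions of collagen and matrix protease genes, 41 rose, 15 fell and 61 did not pass (57 adjusted over the list alone, camera adjusted p = 0.0065 and adjusted p = 0.12 with an estimated correlation), with a COL6A3 region (chromosome 2, 237434878 to 237435409, outside the gene) rising from 0.743 ± 0.19 to 40.5 ± 0.055. The same COL6A3 region stood at 23.1 ± 4.1 in EM3 and was also high in EM2, so its rise from E is not particular to M1. NF-kB and cytokine genes had 28 regions that rose, 13 that fell and 39 that did not pass (41 adjusted over the list alone, adjusted p = 0.012 and adjusted p = 0.61 with an estimated correlation), and a region near IL1B rose by 5.27 while one near IL1A changed by -4.81. This cytokine call was lost without E replicate 1 (adjusted p = 0.18, within 0.00036 to 0.61 over the alternatives). Endothelial markers had 16 regions that rose, 6 that fell and 16 that did not pass (23 adjusted over the list alone, adjusted p = 0.034 and adjusted p = 0.39 with an estimated correlation); ERG was at 4.56 and TIE1 at -2.50. With the 10 Mb window median removed the cytokine (adjusted p = 0.086) and endothelial (0.051) calls were lost, and within 1 kb of gene ends the collagen (0.64) and cytokine (0.17) calls. Without E replicate 1, the regions moving against their list in M1 numbered 3 for endothelial markers, 3 for desmosomes, 2 for basal genes and 1 for keratins.

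In all, 28812 of 65771 regions differed between M1 and E at an adjusted p under 0.05, 12881 higher and 15931 lower in M1. Without E replicate 1 the count was 24656.

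**Figure D3:**
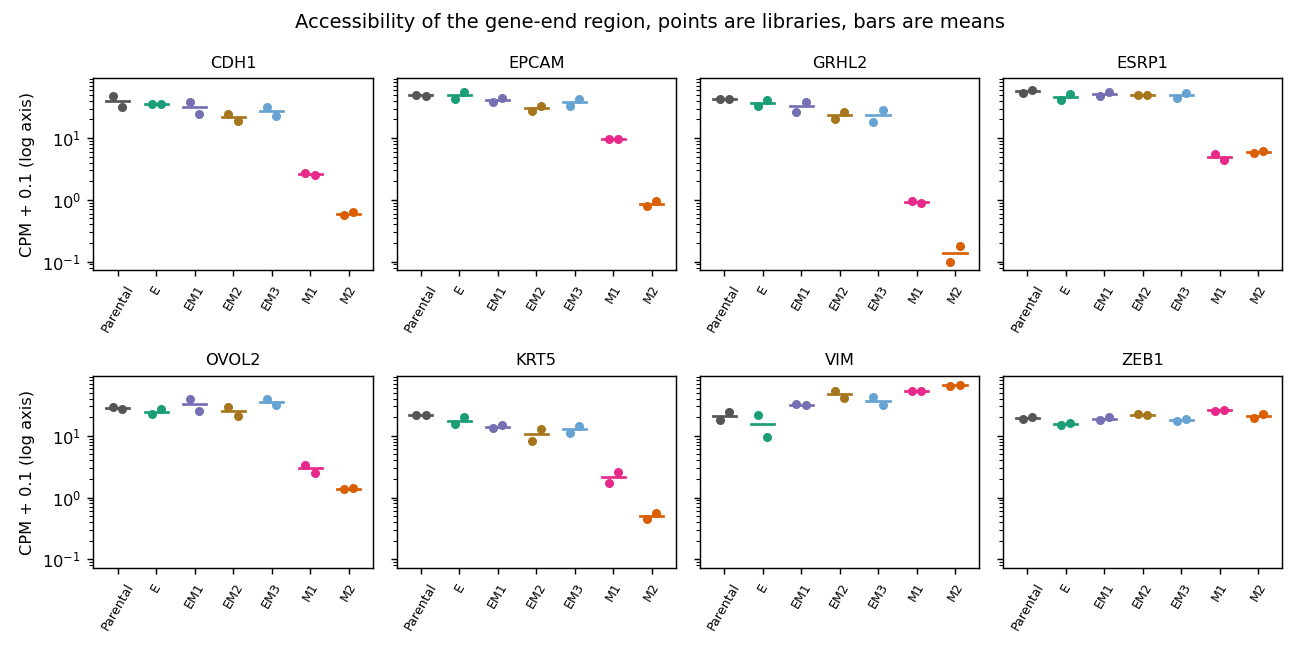
Accessibility (CPM + 0.1, log axis) of the gene-end region of 8 genes in the 7 groups on the x axis. The region is the one with the highest mean log2 CPM among those within 1 kb of a gene end. Points are libraries and horizontal bars are group means; at CDH1, EPCAM, GRHL2, ESRP1, OVOL2 and KRT5 both M clones lie below all other groups.

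M2 was compared with E in the same way and differed at more regions than M1 did. CDH1 accessibility at the same region was 0.496 ± 0.054 in M2, a log2 change of -6.12 from E, and EPCAM was at 0.764 ± 0.11 against 49.8 ± 9.3 in E (-5.98). GRHL2 had 1 count in both M2 libraries together against 648 in E, a ratio of 815 (95% exact interval 146 to 32200). VIM rose to 65.3 ± 1.8, a log2 change of 2.07. TWIST1 (0.40), KRT8 (0.48), RUNX2 (-0.23) and CBFB (0.19) did not pass in the main fit, though KRT8 passed with DESeq2 (0.54). ZEB1 passed at 0.42, but not with library totals (0.28) or with the 10 Mb window median removed (0.09). With that median removed CBFB passed as a rise (1.02). FN1 rose by 1.02, and stood at 0.90 without E replicate 2. The gene-end region of SNAI2, which encodes the EMT transcription factor Slug (chromosome 8, 48921685 to 48922125, outside the gene), was at 34.8 ± 1.6 in M2 and 18.0 ± 7.1 in E, a log2 change of 0.95 that did not pass without E replicate 2 (0.51).

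Several regions had no counts at all in M2, and counts alone cannot tell closed chromatin from lost DNA. With a floor of 3 counts over the group, accessibility was at least 225-fold lower in M2 than in E near NEGR1 (chromosome 1, 72284432 to 72285320, outside the gene), at least 184-fold lower at an end of RAB38 and at least 117-fold lower at an end of PCDH10, a protocadherin. SEL1L2 had 3 counts against 1243, a ratio of 521 (95% exact interval 178 to 2530). It lies at 13995038 on chromosome 20, between windows that were lower in M2 than in Parental as a whole. Their median log2 differences were -5.12 (12 to 13 Mb) and -4.86 (15 to 16 Mb). Among the rises, GALNT6 went from 1.69 ± 0.53 to 16.4 ± 3.2 and ESR2 from 2.67 ± 0.51 to 24.3 ± 9.5. SHROOM3, ESYT2 and ITPRIP rose by 3.34, 3.41 and 3.14, and without E replicate 1 by 5.01, 5.50 and 4.82. The M2-like signal in E replicate 1 raises the E mean where M2 is high. The sizes of rises in M2, and which of them rank largest, therefore depend on that library.

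Epithelial identity, basal and desmosome lists fell in M2, while the shifts of the keratin and mesenchymal lists did not pass. Of 133 epithelial identity regions, 16 rose, 81 fell and 36 did not pass (98 adjusted over the list alone, camera adjusted p = 2.1e-07 and adjusted p = 0.12 with an estimated correlation), with ELF3 at -5.26. Basal and p63-linked genes had 9 regions that rose, 40 that fell and 32 that did not pass (50 adjusted over the list alone, adjusted p = 0.0075 and adjusted p = 0.39 with an estimated correlation), with CDH3 at -4.86; within 1 kb of gene ends this call was lost (adjusted p = 0.072). Desmosome genes had 15 that rose, 43 that fell and 41 that did not pass (58 adjusted over the list alone, adjusted p = 0.022 and adjusted p = 0.39 with an estimated correlation), with PKP1 at -6.30 and PKP2 at -6.65. This desmosome call was lost without E replicate 2 (adjusted p = 0.056, within 0.0011 to 0.39 over the alternatives). Keratins had 8 regions that rose, 17 that fell and 22 that did not pass (25 adjusted over the list alone), and the list shift did not pass (adjusted p = 0.43). Mesenchymal effectors had 63 regions that rose, 39 that fell and 69 that did not pass (102 adjusted over the list alone), and this shift did not pass (adjusted p = 0.16); ITGA5 was at -3.85.

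The other 9 lists passed in no comparison with E, with adjusted p between 0.062 and 1.0. In M2 their regions rose and fell as follows: 37 and 60 of 154 for the TGF-beta pathway (100 adjusted over the list alone), 30 and 49 of 136 for the Wnt pathway (79), 31 and 29 of 113 for Hippo and TEAD genes (59), and 18 and 33 of 77 for stem and progenitor genes (51). The counts were 18 and 15 of 48 for RUNX and CBFB genes (34 adjusted over the list alone), 16 and 15 of 51 for EMT transcription factors (31), 15 and 9 of 37 for luminal identity (24), 12 and 3 of 23 for HOX genes (15) and 27 and 8 of 58 for housekeeping genes (35). In the 20 list tests that passed, the median, the mean and the test had the same sign; in 27 of the 80 that did not pass, they differed. In all, 39801 regions differed between M2 and E, 19208 higher and 20593 lower in M2, and 38005 did without E replicate 1.

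M1 and M2 overlapped in the regions that differed from E but also differed from each other. Regions higher in both numbered 5757, where 3762 would be shared by independent lists, and regions lower in both numbered 10017 against 4988. Both comparisons use the same E libraries, which were not divided between them, so part of the excess can come from these libraries. The overlap is not given without E replicate 1. Simulated draws without change called no region and say nothing about the excess. Across regions the M1 and M2 changes had a covariance of 1.564, against 0.076 in those draws, and a correlation of 0.43, against 0.51 in the draws. The draws hold only variation between libraries, with no real difference of E from the other groups and no M2-like signal in E. They therefore cannot say how much of the covariance comes from E. CDH1 was lower in M2 than in M1 (log2 change -2.29, edgeR adjusted p = 0.0014), as were EPCAM (-3.61, adjusted p = 6.9e-07) and KRT5 (-2.33, adjusted p = 0.00084), while ESRP1 did not pass (0.28, adjusted p = 0.27). Between M2 and M1, 37022 regions differed, 17899 higher and 19123 lower in M2. Mesenchymal effectors had 34 regions higher and 70 lower in M2 than in M1 (104 adjusted over the list alone), collagen and matrix proteases 19 and 54 (73), and desmosome genes 37 and 22 (60).

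**Figure D4:**
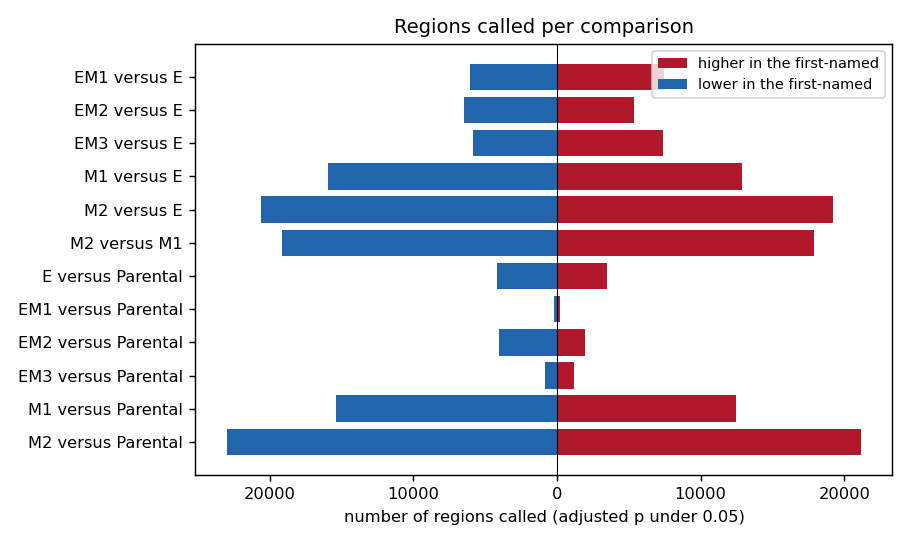
Number of regions past an adjusted p of 0.05 in 12 comparisons, with regions higher in the first-named group to the right of 0 and lower ones to the left. M2 versus Parental has the most, 44093, and EM1 versus Parental the fewest, 413.

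EM1 and EM3 were each compared with E to ask how clones named EM differed from it. The epithelial gene-end regions that fell in M1 and M2 did not pass the test in either clone. CDH1 was at 31.3 ± 9.2 in EM1 and 27.2 ± 7.0 in EM3 against 35.8 ± 0.15 in E, and EPCAM, GRHL2, ESRP1 and OVOL2 did not pass either. With the 10 Mb window median removed, OVOL2 passed in EM3 as a rise (0.80). GRHL2 was lower in EM3 (23.4 ± 7.4) than in E (37.2 ± 5.2), a log2 change of -0.68. This GRHL2 change passed with loess offsets (-0.78) and with a replicate block, and stood at -1.08 without EM3 replicate 2. VIM rose to 31.7 ± 0.82 in EM1 (log2 change 1.03) and 36.8 ± 7.0 in EM3 (1.24). The VIM rise no longer passed without E replicate 2 (0.46 in EM1, 0.67 in EM3), without EM1 replicate 1 (1.00), without EM1 replicate 2 (0.99) or without EM3 replicate 1 (1.03). With the 10 Mb window median removed VIM stood at -0.03 in EM1 and 0.19 in EM3.

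Other loci changed by more in these clones. GUCY1B1 rose from 0.826 ± 0.55 in E to 17.1 ± 3.9 in EM1 and 14.6 ± 1.3 in EM3. A region inside COBL, an actin nucleator (chromosome 7, 51019162 to 51019916), rose from 4.45 ± 0.23 to 53.8 ± 6.0 and 55.6 ± 7.3. A region outside CD44, a cell-surface receptor for hyaluronan (chromosome 11, 35110972 to 35112324), rose from 19.5 ± 3.0 to 127 ± 18.0 and 127 ± 1.0. In EM3 a region inside PAX6 rose from 5.23 ± 1.3 to 44.1 ± 1.6. At an end of TBX3, a T-box transcription factor (chromosome 12, 114684075 to 114684968), accessibility fell from 31.0 ± 23.0 in E to 1.59 ± 0.27 in EM1 and 0.83 ± 0.11 in EM3, log2 changes of -4.29 and -5.23 that were -3.20 and -4.14 without E replicate 1. In the window that holds TBX3 (114 to 115 Mb), the median log2 difference from Parental was 2.12 in E, -0.34 in EM1 and 0.22 in EM3. The TBX3 difference thus lies where E, and not EM1 or EM3, was far from Parental. A region near ANKRD1, a target of YAP, fell from 34.3 ± 5.3 to 4.56 ± 0.23 in EM1.

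Interferon, AP-1 and keratin lists shifted downward in both clones, but none of these shifts passed with the 10 Mb window median removed (adjusted p = 0.26 and 0.42 for interferon in EM1 and EM3, 0.18 and 0.086 for AP-1, 0.51 and 0.66 for keratins), and within 1 kb of gene ends AP-1 (0.32 and 0.25) and keratins (0.17 and 0.26) did not pass. Of 68 regions of interferon and antigen presentation genes, 7 rose, 18 fell and 43 did not pass in EM1 (27 adjusted over the list alone, camera adjusted p = 0.0065 and adjusted p = 0.12 with an estimated correlation). In EM3 6 rose, 11 fell and 51 did not pass (17 adjusted over the list alone, adjusted p = 0.031 and adjusted p = 0.25 with an estimated correlation). Regions near OAS1, an antiviral enzyme, stood at -5.10 in EM1 and -4.39 in EM3. AP-1 factors had 2 regions that rose, 11 that fell and 46 that did not pass in each clone (14 adjusted over the list alone in each, adjusted p = 0.016 and 0.015, and adjusted p = 0.45 with an estimated correlation in each), with a FOS region at -1.17 and -1.04 and a JUN region at 2.12 and 1.82. Without E replicate 1, 1 AP-1 region rose and 6 fell in EM1, and 1 rose and 3 fell in EM3. Keratins had 5 regions that fell, 0 that rose and 42 that did not pass in each clone (4 and 2 adjusted over the list alone, adjusted p = 0.019 and 0.039, and adjusted p = 0.45 and 0.54 with an estimated correlation), with KRT6A at -0.81, which was lost in EM1 with the window median removed, and -0.89.

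Without E replicate 1, 1 keratin region rose in each clone and 2 fell in EM1 and 1 in EM3. Without E replicate 2 the keratin calls were lost (adjusted p = 0.12 in EM1 and 0.18 in EM3, within 0.013 to 0.66 over the alternatives), as was the interferon call of EM3 (adjusted p = 0.12, within 0.014 to 0.42). Markers of blood cells had 7 regions higher, 1 lower and 19 not passing in EM1 (11 adjusted over the list alone, adjusted p = 0.042 and adjusted p = 0.39 with an estimated correlation), among them CSF1R at 1.54. That call was lost without E replicate 1 (adjusted p = 0.079) and without E replicate 2 (adjusted p = 0.10), with the window median removed (0.32) and within 1 kb of gene ends (0.16), with a range of 0.042 to 0.39 over the alternatives. In all, 13478 regions differed between EM1 and E, 7464 higher and 6014 lower in EM1, and 13236 between EM3 and E, 7405 higher and 5831 lower in EM3. Against Parental, EM1 differed at 413 regions and EM3 at 2047, so a difference from E need not be a change in the EM clone. The EM1 count was 7939 without E replicate 1, 6804 without EM1 replicate 1 and 6833 without EM1 replicate 2; the EM3 count was 8091 without E replicate 1, 6006 without EM3 replicate 1 and 5891 without EM3 replicate 2. Without E replicate 2 fewer regions were higher than lower, 42.0% of those called in EM1 and 40.9% in EM3. EM1 and EM3 differed from each other at 31 regions.

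EM2 was compared with E in the same way. At an end of CHI3L1, which encodes a secreted chitinase-like glycoprotein (chromosome 1, 203186483 to 203187287), accessibility fell from 50.2 ± 0.71 in E to 4.11 ± 0.30 in EM2. LURAP1L (chromosome 9, 12771851 to 12772297, outside the gene) fell from 62.3 ± 5.9 to 5.63 ± 1.9 and SLCO4C1, an organic anion transporter, from 25.2 ± 7.6 to 1.08 ± 1.1. ADARB2 rose from 2.71 ± 0.054 to 27.5 ± 4.6. A region inside ZFP42, a pluripotency marker (chromosome 4, 188002249 to 188002859), was at 2.31 ± 0.0009 in E and 18.7 ± 1.3 in EM2. Parental, EM1 and EM3 were near the EM2 level at this ZFP42 region, and M1 and M2 were low there like E. The ZFP42 difference is therefore a low level in E and not a gain particular to EM2. The COL6A3 region that rose in M1 stood at 27.3 ± 4.4 in EM2, a log2 change of 5.17, and VIM rose to 47.0 ± 7.9 (1.59, or 0.48 and not past the threshold with the 10 Mb window median removed).

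Epithelial loci in EM2 changed in part. A region inside CDH1 (chromosome 16, 68778493 to 68779242) fell from 34.3 ± 0.19 to 8.57 ± 0.45, and a region outside ELF3 fell from 43.9 ± 2.1 to 7.94 ± 1.1. The gene-end region of CDH1 was at 21.5 ± 4.2 and did not pass without a replicate block. EPCAM fell by 0.73, which did not pass without E replicate 2 (-0.62) or EM2 replicate 1 (-0.58), or with the 10 Mb window median removed (-0.38). Epithelial identity genes had 8 regions that rose, 18 that fell and 107 that did not pass (27 adjusted over the list alone), and the list shift did not pass (camera adjusted p = 0.26). Desmosome genes had 1 region that rose, 10 that fell and 88 that did not pass (7 adjusted over the list alone, adjusted p = 0.039 and adjusted p = 0.39 with an estimated correlation), with PKP1 at -1.73. Interferon genes had 3 that rose, 8 that fell and 57 that did not pass (10 adjusted over the list alone, adjusted p = 0.031 and adjusted p = 0.25 with an estimated correlation), with IFIT2 at -3.41. Both calls were lost without E replicate 2 (adjusted p = 0.50, within 0.0027 to 0.51 over the alternatives, and 0.12, within 0.03 to 0.32). With the 10 Mb window median removed both were lost as well (adjusted p = 0.51 and 0.32), and within 1 kb of gene ends the desmosome call (0.26). Without E replicate 1, 5 epithelial identity regions rose and 13 fell, and 5 interferon regions rose and 9 fell. In all, 11824 regions differed between EM2 and E, 5333 higher and 6491 lower in EM2. The count was 7471 without E replicate 1, 5977 without EM2 replicate 1 and 6704 without EM2 replicate 2.

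The place of the EM clones between E and the M clones was measured at regions where both M clones differed from E by at least 2 log2 units, chosen on one replicate and measured on the other, with 0 for the E level and 1 for the mean of M1 and M2. At regions lower in M the median position, averaged over the 2 choices of replicate, was -0.02 ± 0.03 for EM1, 0.03 ± 0.01 for EM3 and 0.17 ± 0.00 for EM2 (SD over these choices, n = 2), and Parental was at -0.06 ± 0.04. At regions higher in M the positions differed between the 2 choices of replicate, which also differ in their regions. Measured on replicate 2 at 714 regions, EM1 was at 0.21, EM2 at 0.35, EM3 at 0.26 and Parental at 0.09. Measured on replicate 1, where E carries the M2-like signal, at 2265 regions, they were at -0.28, -0.24, -0.05 and -0.60. No test was run on these positions.

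The M clones were compared with the EM clones with 1 value per clone, 2 clones against 3. EM1 and EM3 differed from each other at 31 regions, against 8030 between EM2 and EM1. Libraries of EM1 correlated with those of EM3 at 0.94 to 0.97, about as replicates did within EM1 (0.95) and EM3 (0.96). On chromosome 20 from 3 to 4 Mb the median log2 difference from Parental was -1.07 in EM1 and -1.06 in EM3. It was 0.17 in E and 0.06 in EM2. EM1 and EM3 were thus closer to each other than other pairs of clones were. The spread among the EM clones is likely understated, and too many regions may pass. Regions at ends of some epithelial genes were lower in the M clones, while those of EPCAM (-2.80, edgeR adjusted p = 0.15) and KRT5 (-3.24, adjusted p = 0.068) did not pass. With DESeq2 these 2 did pass (-2.76, adjusted p = 0.011, and -3.21, adjusted p = 0.00025). They also passed with libraries as replicates, which takes libraries of 1 clone as independent. With any one EM clone left out they did not pass (edgeR adjusted p from 0.16 to 0.36). They stood at -5.52 and -4.86 without clone M1, and at -1.92 and -2.51 without clone M2. Each of these fits holds 1 M clone, so only the EM clones supply the spread. ESRP1 was at 5.38 ± 0.69 (n = 2 clones) against 50.3 ± 1.7 (n = 3 clones), a log2 change of -3.22 (edgeR adjusted p = 0.019), and OVOL2, a repressor of EMT, changed by -3.93 (adjusted p = 0.021). AMOTL2 changed by -6.89 and RBBP8 by -6.77, the same regions as in M1 versus E. XYLT1 (chromosome 16, 17471251 to 17472014, outside the gene) rose from 4.24 ± 1.5 to 48.1 ± 15.0 and a region inside ADAM12, a matrix protease, rose by 4.38. Epithelial identity had 0 regions that rose, 33 that fell and 100 that did not pass (57 adjusted over the list alone), desmosomes 0, 16 and 83 (25 adjusted over the list alone) and collagens and proteases 8, 0 and 109 (8 adjusted over the list alone). In all, 4641 of 65147 regions differed, 1304 higher and 3337 lower in the M clones. Leaving out 1 clone changed this count: with edgeR it was 0 without EM1, EM2 or EM3 (10326, 14675 and 10738 regions at an unadjusted p under 0.05), so every gene named here was also lost, while ESRP1 stood at -3.17, -3.22 and -3.24 and OVOL2 at -3.92, -4.05 and -3.79 in these fits with fewer clones. Without clone M1 or M2 the M side holds 1 clone and only the EM clones supply the spread. The counts of these fits are therefore not set beside the others here. DESeq2 with all 5 clones gave 15304.

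Regions that set the EM clones apart from both E and the M clones were counted from clone means, as regions where the lowest of one side was at least 1 log2 unit above the highest of the other. There were 1348, 478 higher and 870 lower in the EM clones. Among the other 9 ways to split the 6 clones 3 against 3, EM2, M1 and M2 against E, EM1 and EM3 gave 1213 and EM1, EM3 and M1 against E, EM2 and M2 gave 374. The order of the first 2 splits depended on single libraries. Without E replicate 1, which carries M2-like signal, 994 regions separated the EM clones (522 higher, 472 lower) and 1387 the other split. Without EM2 replicate 2 the counts were 1211 and 1590. Without E replicate 2 they were 1948 and 1089. A region inside RNF122 (chromosome 8, 33550241 to 33550677) was at 24.9 ± 3.0, 17.4 ± 3.6 and 25.9 ± 2.7 in EM1, EM2 and EM3, against 3.07 ± 0.46 in E, 2.70 ± 0.086 in M1 and 0.286 ± 0.40 in M2. A region near HEMK1 (chromosome 3, 50567394 to 50567921, outside the gene) was at 2.50 ± 0.012, 1.86 ± 0.86 and 2.91 ± 0.59 in the EM clones, against 17.6 ± 2.1 in E and 19.2 ± 0.18 in M1. At another such region, near PDPN, the E libraries lay far apart (6.78 ± 7.6). These examples were chosen after their values were seen. Parental was near the EM clones at these regions: its median difference from their mean was -0.05 at the higher and 0.17 at the lower regions, and from E it was 1.70 and -2.03.

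Each clone was also compared with Parental, the unselected line. EM1 differed least and M2 most. CDH1 was at 39.9 ± 12 in Parental and changed by -3.99 in M1 and -6.28 in M2 (edgeR adjusted p = 9e-07 and 4.9e-08). VIM was at 21.1 ± 4.8 in Parental and rose by 1.33 in M1 and 1.63 in M2 (adjusted p = 0.0017 and 0.0002), while EM1 and EM3 did not pass at either gene. EM2 passed at both, with CDH1 at -0.90 (edgeR adjusted p = 0.048) and VIM at 1.15 (adjusted p = 0.021). CDH1 no longer passed without EM2 replicate 1 (-1.11), EM2 replicate 2 (-0.71) or Parental replicate 1 (-0.56). The CDH1 call was also lost with the 10 Mb window median removed (-0.715), with loess offsets (-0.905) and with the M2 libraries and E replicate 1 left out (-0.879). VIM no longer passed without EM2 replicate 1 (0.97), Parental replicate 1 (0.94) or Parental replicate 2 (1.36). E did not pass at either gene with all libraries. The direction of VIM in E depended on the setting. VIM stood at -0.44 with all libraries, -1.15 without E replicate 1, 0.10 without E replicate 2 and 0.45 with the 10 Mb window median removed. Of 133 epithelial identity regions, 8 rose and 85 fell in M1 (97 adjusted over the list alone), 13 rose and 91 fell in M2 (108), 1 rose and 24 fell in EM2 (31), 0 rose and 7 fell in EM3 (15), 1 rose and 13 fell in E (14), and 0 rose or fell in EM1 (0). Mesenchymal effectors had 77 regions that rose and 15 that fell in M1 (102 adjusted over the list alone), 72 and 49 in M2 (121) and 15 and 15 in E (37).

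Against Parental, 27879 regions differed in M1 (12496 higher, 15383 lower), 44093 in M2 (21144 higher, 22949 lower), 7610 in E (3463 higher, 4147 lower), 6043 in EM2 (1987 higher, 4056 lower), 2047 in EM3 (1219 higher, 828 lower, but more lower than higher without Parental replicate 1, with 39.8% higher, or Parental replicate 2, with 33.8%) and 413 in EM1 (224 higher, 189 lower). The smaller counts depended on single libraries. For EM1 the count was 20 and 12 without EM1 replicate 1 and 2, and 7 and 2 without Parental replicate 1 and 2. For EM3 it was 194, 387, 108 and 142 without EM3 replicate 1, EM3 replicate 2, Parental replicate 1 and Parental replicate 2, and for EM2 it was 2393, 3880, 2173 and 2519 for the corresponding libraries. For E it was 3391 without E replicate 1, 2264 without Parental replicate 1 and 1235 without Parental replicate 2, and without E replicate 2 62.5% of the regions called were higher.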

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

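The difference between M2 and M1 had been planned as a comparison, and all tests of explanations in this part were chosen after the result was seen. The gene-end region of SNAI2 stood out because M1 and M2 moved apart from E in opposite directions: the log2 change was -0.97 in M1 and 0.95 in M2, and the difference itself was 1.93 (edgeR adjusted p = 5.9e-05), higher in both M2 libraries than in both M1 libraries. The M1 change was no longer past the threshold without E replicate 1 (-0.50) or M1 replicate 1 (-0.89), or with the 10 Mb window median removed (-0.56), and the M2 change without E replicate 2 (0.51). Across regions, 4454 were called in opposite directions in M1 and M2 with their difference also called, 2192 higher in M1 and 2262 higher in M2. No biological explanation was tested for these.

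E replicate 1 resembled M2. Lower depth of that library is argued against. Over the 65758 regions used to fit the weight of M2, E replicate 2 thinned to the same total correlated with M2 at 0.42. E replicate 1 did at 0.59 over these regions, which is another basis than the correlations of single libraries given above. M2 material in the library is a candidate explanation: at 12 regions without counts in Parental, EM1, EM2, EM3 and M1 it had 23.12% of the M2 level, near the weight of 25.2% fitted on all other regions. Whether cells, DNA or sequencing indices were mixed stays open, as does a subpopulation in E with M2-like chromatin. No biological explanation was tested.

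M2 stood apart from the other groups. Chromosome-scale copy number as the whole cause is argued against, since 36961 regions were still called in M2 versus E with the median of each 10 Mb window removed (39801 before, 31785 in both). Another origin of the M2 cells stays open: 12 regions had at least 100 counts in M2 and 0 in Parental, EM1, EM2, EM3 and M1, such as the STK11 end (chromosome 19, 1205454 to 1205878; 301 and 557 counts in M2) and a region inside ERAP1 (844 and 1335 counts). With M2 left out, E had 1 such region (ERAP1, 187 and 18 counts) and the remaining groups had 0. With M2 kept in, E had 0. The ERAP1 region is among the 12 of M2, where E replicate 1 held M2-like signal, so it is no separate example. The test still did not decide, since a sub-line that kept DNA lost from the others would give the same counts. That explanation stays open as well. Some of the 12 lie close together on chromosome 9, from 21591630 (near IFNE) to 23826627 (inside ELAVL2). No biological explanation was tested.

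For the M clones against the EM clones, there are 10 splits of the 5 clones, 2 against 3, too few for a share under 0.05. Only the real split gave 4641 regions, and the highest of the others gave 0.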

How the results depend on the processing

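The settings without the M2 libraries and E replicate 1, the list tests without single E libraries, and the counts of separating regions without single libraries, were chosen after the data were seen; all others had been planned. Every count of M1 or M2 against E, Parental or each other stayed within 1.5 times its value under every setting tried; leaving out each library gave 21605 to 26850 for M1 versus E and 31006 to 38005 for M2 versus E. Counts of the other comparisons moved, and the cause was not tested. With the M2 libraries and E replicate 1 left out, the counts were 8191 (EM1 versus E), 7707 (EM2 versus E), 8323 (EM3 versus E), 3321 (E versus Parental), 668 (EM1 versus Parental) and 3090 (EM3 versus Parental). With only the 4 libraries compared they were 6493, 4783 and 7023 for EM1, EM2 and EM3 versus E, 4447 for E versus Parental, 1132 for EM1 versus Parental and 5469 for EM3 versus Parental. With the replicate block they were 13107 (E), 1601 (EM1), 10811 (EM2) and 5482 (EM3), each versus Parental. Versus E, the gene ends of CDH1 (-0.763), GRHL2 (-0.672), KRT5 (-0.743) and ZEB1 (0.476) in EM2 newly passed with the block. So did those of GRHL2 in EM3 (-0.693), FN1 in M1 (0.729) and KRT8 in M2 (0.479). Over 21 pairs of groups, the deviations of same-numbered libraries correlated at 0.02 to 0.59, with 2 at or below 0.1. Both of these low pairs involve E (0.02 with M1, 0.07 with M2), whose replicate 1 carried M2-like signal. The numbers were not taken as pairing the libraries in the main fit, and whether they mark shared batches stays open. If they do, the main fit can miss differences such as those just named. DESeq2 gave 1197 for EM1 and 3643 for EM3 versus Parental. Leaving out each library gave 6804 to 13807 (EM1 versus E), 5977 to 11565 (EM2 versus E), 5891 to 13250 (EM3 versus E), 1235 to 9269 (E versus Parental), 2 to 20 (EM1 versus Parental), 2173 to 3880 (EM2 versus Parental) and 108 to 387 (EM3 versus Parental); fewer libraries also lower the power.

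M clones versus EM clones gave 15304 with DESeq2, 43832 with libraries as replicates and 47481 with libraries as replicates and a replicate block, which take libraries of 1 clone as independent. Without clone EM1, EM2 or EM3 edgeR gave 0 each (10326, 14675 and 10738 at an unadjusted p under 0.05), without clone M1 33502 and without clone M2 10118. The fits without clone M1 or without clone M2 each hold 1 M clone, so only the EM clones supply the spread. The counts of these fits cannot be set beside the others, and nothing is concluded from them. Of 100 list tests, 20 passed; 11 did with the 10 Mb window offset, 9 of them among the 20, and 0 with an estimated correlation (smallest adjusted p 0.092). Of the 20, 19 could be tested within 1 kb of gene ends and 9 passed there; 18 passed without E replicate 1 and 13 without E replicate 2. With a log2 limit of 1 the positions at regions lower in M were 0.15 for EM2 and 0.01 for EM3, and with library totals 0.02 for EM3. With a gap of 2 log2 units, 202 regions separated the EM clones and 236 the other split with the most; leaving out each library gave 994 to 1948. With the window offset, 3 named regions reversed: VIM in EM1 versus E (-0.032, from 1.03), EHF in EM2 versus E (-0.016, from 0.95) and KRT8 in M2 versus Parental (-0.052, from 0.55). Of 8415 values of named regions under alternatives, 7669 were the same, 581 were no longer and 63 newly past the threshold, and 99 moved. Which direction held more regions turned with loess offsets in EM1 versus Parental (44.6% higher), EM3 versus Parental (45.6%), M2 versus E (53.9%), M2 versus M1 (53.7%) and M2 versus Parental (53%), with the DESeq2 test and size factors in M2 versus E (50.9% and 51.1%), and in EM2 versus E with the M2 libraries and E replicate 1 left out (51.0%). Motif analysis and its alternatives were not run, since no genome sequence was used here.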

Other observations

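The test in this part was chosen after the attachment of the lists was seen. The authors' 7 peak lists are mostly attached to libraries of clones other than those they are named for, 1 being attached to its own clone. That each list belongs to the clone in its name may explain their content: 7 of 7 lists overlapped the regions in the way that correlated best with the group in their name (0.23 for E to 0.65 for M2).

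Some megabase windows moved together against Parental. On chromosome 9 between 27 and 28 Mb (10 regions, near TEK) the median log2 difference was 5.26 in EM2, 5.55 in M1, 4.99 in M2, 1.46 in E, -0.29 in EM1 and -0.12 in EM3. The medians of whole chromosomes had an SD of 0.35 in M2 and between 0.06 and 0.15 in the other clones, with chromosome 13 at -0.70 and chromosome 19 at 0.59 in M2.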
